A study of Drosophila melanogaster with 4 samples.

How the data were processed

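RNA was extracted from tracheae of third-instar Drosophila melanogaster larvae, amplified, labelled with Cy3 or Cy5 and hybridised to 4 two-colour arrays, with 20 pairs of tracheae per extract per the labels. Larvae were 10 days old and kept at 22 °C. Each array compared larvae that carried the tracheal GAL4 driver NP2610 and a UAS-PGRP-LE transgene with larvae of the driver strain. The labels name 2 biological replicates, each with a second array called its technical replicate, and the design text states that dyes were swapped. The dye labels give Cy5 for both channels of the first biological array, and the arrays of replicate 2 have opposite dyes.

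The values analysed here are those the authors deposited: for each array a log2 ratio per spot for 32448 numbered spots, with no missing value and no gene name. The normalization method is not stated in the labels. Per array, 2.95 to 8.17% of spots held the most frequent value of their block of rows, against 2.34 to 5.80% with the block borders shifted, so a per-block step by the authors is possible but not stated. Array medians were not at 0 after it. The authors' deposited table lists 244 genes that they selected with the software named in the design text, GeneTraffic and SAM, with thresholds that are not given. For each gene it holds the mean log2 ratio and the standard deviation over valid spots (also on the log2 scale), their quotient as a ratio, and another column, the number of valid spots, from 6 to 16. Its hybridisation group names PGRP-LE and a driver with the digits of NP2610 in another order.

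Spots were tied to genes by their values. Rows 1 and 2, 3 and 4 and so on behaved as duplicate spots, giving 16224 spot pairs in 48 blocks of 338 pairs. For 116 of the 134 listed genes with 8 valid spots, the mean and standard deviation of the 8 values of at least 1 spot pair equalled the authors' mean and standard deviation within 0.005. Shifted means gave 6.4 such genes, and turning the sign of any array gave at most 21. The 4 columns therefore run in the same direction as the authors' table and are on its log2 scale. That this direction is PGRP-LE over driver control rests on the table's group name, since the dye labels do not settle it. Genes with 8 or 7 valid spots and a single matching spot pair were named, 131 in all, of which 1.5 are expected to be wrong if chance matches arise only in genes whose own spots find no match. Chance matches were more frequent for 7 valid spots, where 29 of 31 genes had a match and shifted means gave 9.4, than for 8. In a test on 200 known spot pairs 186 were recovered as the single match. Each pair's own values were always found in this test, so a wrong single match could not occur. It measures only how often a match is unique. As a separate check, 17 of 17 neighbouring matched pairs stood in ascending order of their CG identifiers, sorted as text and not by number. The median rank distance was 1 against 70 after shuffling (permutation p = 0.0001, the smallest that 10000 shuffles can give). The spot that the authors left out could be located for 19 of the 21 matched genes with 7 valid spots, 17 of them on the technical array of replicate 1. Spot pair values average both duplicates, and an alternative added after the data were seen leaves out these 19 spots. The 73 genes with 6 valid spots were left unmatched, since the table does not say which array lacks valid spots. Of these, 50 matched when the technical array of replicate 1 was left out, against 6.5 by chance. Gene symbols came from a RefSeq gene table of assembly Release 6, by locus tag for 227 genes and by synonym for 13, and 4 kept their identifier as deposited.

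The test fixed before the data were examined averaged the 2 arrays of each replicate, fitted limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend) to the mean log2 ratio against 0 over 16224 spot pairs with n = 2, and adjusted the two-sided p by Benjamini-Hochberg, with a threshold of 0.05. The control RNA is in the ratio, so the spread of the control between animals is not measured separately, and the labels do not say whether its extracts were separate. The fit had 1 residual and 4.97 prior degrees of freedom. Simulated data were made by shuffling the spot pairs within each array and adding the same change to all 4 arrays. This removes dependence between arrays and variation of the change between replicates, so recovery in the real data may differ. With 200 of the 16224 spot pairs changed, limma called 0% of changes of 1 on the log2 scale. It called 30% of changes of 2 and 83% of changes of 3. With each array centred it called 0.5% of changes of 1, 19.5% of changes of 2 and 97.5% of changes of 3, the last with 31 false calls. With 200 of the 2178 centred spot pairs with close duplicates changed, a larger share, it called 53.5% of changes of 1 with 17 false calls. A one-class SAM-type statistic over the 4 arrays used the median standard error as its constant and all sign changes as its null. On shuffled arrays that were centred, with upward changes only, it recovered 83.5% of changes of 3 with 6 false calls. The reported run of this statistic used the arrays as deposited, not centred, so its recovery there was not measured. For arrays, the small number limits the precision, and spot intensities were not used here, so no signal over background can be given.

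Of the results fixed in advance, the level of PGRP-LE and the camera and fry tests of gene lists could not be computed, since only listed genes have names. PGRP-LE is not among them. In their place, the members of 34 gene lists (pathways, stress and cell type markers, written before the data were examined) were counted in the authors' deposited table. For lists with at least 5 listed members, the share of higher members was compared with that of the other listed genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Fit p-values of matched members were also adjusted over the list alone. Named genes follow a rule fixed in advance: PGRP-LE, the antimicrobial peptide genes, the 10 genes with a symbol and the largest rise and fall past the threshold with 1 sign on 4 arrays, places left open going to the sign-keeping genes with the smallest p in each direction, and up to 4 members per list with the smallest p. Alternatives treated the 4 arrays as separate values, with the replicate as a random block or with a dye term, centred or also scaled each array, left out each array, fitted each spot alone, used robust eBayes, a threshold of 0.1 or the SAM-type statistic. Alternatives added after the data were seen kept only the 2178 spot pairs whose duplicates differed by less than 0.5 on every array, with and without centring, or subtracted the median of each position within a block, over all spot pairs or over those not matched to a listed gene. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.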

Results

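The airway epithelium of third-instar Drosophila larvae was profiled on 4 two-colour arrays after PGRP-LE had been overexpressed in it. PGRP-LE is a receptor that binds bacterial peptidoglycan and signals through the Imd pathway, which ends in the NF-kappaB factor Relish and in transcription of antimicrobial peptide genes. The GAL4 driver strain supplied the reference RNA on each array. The arrays form 2 biological replicates, each with a technical array, and every array holds 32448 spots. The comparison asks which transcripts differ in the larval trachea when PGRP-LE is overexpressed, a step the submitters chose in order to activate this pathway; activation itself was not measured separately here. Log2 ratios are given as PGRP-LE over driver control, a direction that rests on the group name of the authors' deposited table and not on the dye labels. Of the listed genes, 131 could be traced to their spots by their values.

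The authors' deposited table lists 244 genes, of which 187 (76.6%) have a higher and 57 a lower mean log2 ratio in PGRP-LE tracheae. In the authors' deposited table the median of the higher genes is 0.92, the largest being 2.05 for CG11983 (4.14-fold), and the median of the lower genes is -0.91, the lowest being -1.65 for the small nucleolar RNA gene snoRNA:U29:54Ed. This list was chosen by the authors on the same arrays, so its counts are not independent evidence of direction.

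Antimicrobial peptide genes, the classical targets of Imd signalling, were the immune group with the most listed members. The authors' deposited table gives all 9 of its antimicrobial peptide genes as higher, out of 21 genes on the fixed list, with a median log2 ratio of 1.48. The attacins, which act on Gram-negative bacteria, stand highest in the authors' deposited table, with 2.02 for AttC (CG4740, 4.06-fold) and 1.84 for AttA (CG10146), while AttD (CG7629) is given as 0.97. The authors' deposited table further holds the cecropin gene CecA2 (CG1367) at 1.68, the diptericin genes DptA (CG12763) at 1.20 and DptB (CG10794) at 0.86, Def (CG1385), which encodes defensin, at 1.07, and the drosomycin-like genes Drsl1 (CG32274) at 1.54 and Drsl4 (CG32282) at 1.48. On their matched spots AttC averaged 2.02 ± 0.02 and AttA 1.75 ± 0.20 (SD, n = 2), both above 1.5 on each of the 4 arrays. Without the AttA spot that the authors left out, AttA averaged 1.95 ± 0.48. Of the other listed genes 178 are higher and 57 lower, so that 9 of 9, the most extreme upward outcome possible, gives p = 0.122 (Fisher's exact test, two-sided, adjusted 0.243 over 2 lists), and the test could not have passed for an upward shift of this list.

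Upstream components of the response were few in the list. The authors' deposited table gives 0.96 for Rel (CG11992), which encodes Relish itself, and 1.17 for PGRP-SD (CG7496), a secreted recognition protein. They are the only listed members of the Imd signalling list, which holds 20 genes, and of the 13 peptidoglycan recognition protein genes. PGRP-SD averaged 1.08 ± 0.18 (SD, n = 2) on its valid spots, with 1.20 in replicate 1 and 0.95 in replicate 2, and 1.49 ± 0.76 when a spot at 3.69 that the authors left out was included. The spot pair beside it belongs to CG34227, also a listed gene. PGRP-LE is not in the list, so its level is not reported. The authors' deposited table also holds BomT3 (CG5778), an immune-induced Bomanin peptide gene, at 0.74, the iron carrier gene Tsf1 (CG6186) at 0.70 and the serpin genes Spn43Ab (CG1865) and Spn55B (CG10913) at 0.80 and 0.77. No member of the Toll pathway list (23 genes) or of the JAK-STAT and Turandot list (19 genes) is listed, and none of the 17 genes of the JNK list. With 244 listed genes on arrays of 16224 spot pairs, lists of this size would hold few or no listed members by chance. Unlisted spots have no names, so absence from the list does not show that these genes were unchanged.

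**Figure D1:**
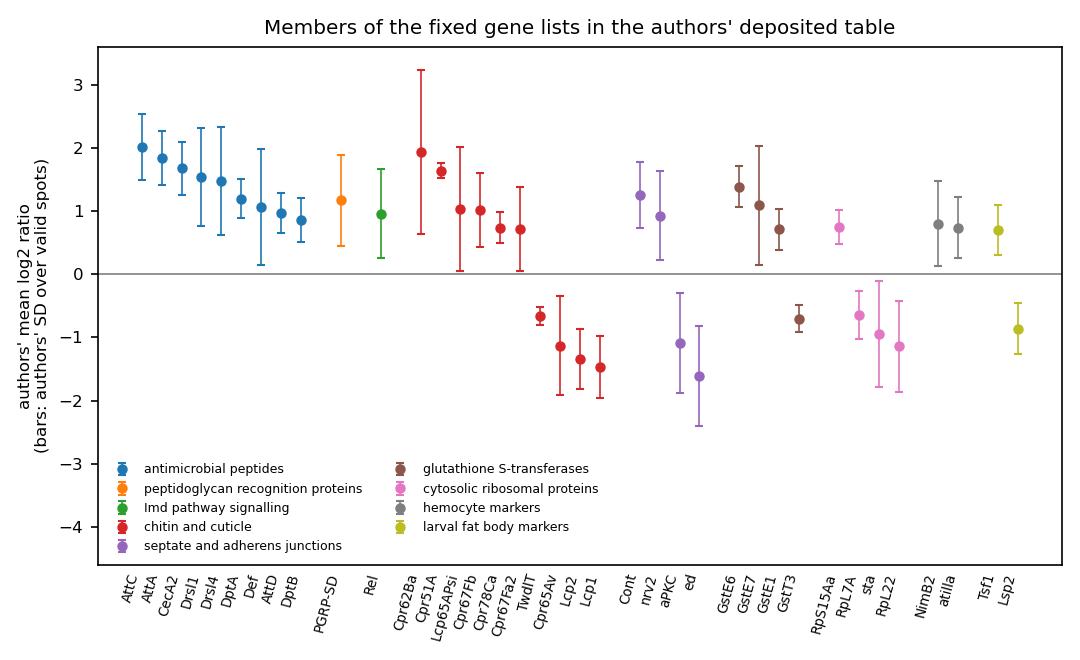
Mean log2 ratio (PGRP-LE over driver control) of the members of 9 gene lists in the authors' deposited table, with the authors' standard deviation over valid spots as bars and 1 colour per list. All 9 antimicrobial peptide genes lie between 0.86 and 2.02, whereas cuticle, junction and ribosomal protein genes lie on both sides of 0.

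Genes of the chitin and cuticle list, which includes the structural proteins of the tracheal lining and body wall, went both ways. The authors' deposited table has 10 of its 161 genes, 6 of them higher, led by Cpr62Ba (CG13934) at 1.94, Cpr51A (CG10112) at 1.64 and Cpr67Fb (CG18348) at 1.02. Lower in the authors' deposited table are 4 members, among them the larval cuticle protein genes Lcp1 (CG11650) at -1.47 and Lcp2 (CG8697) at -1.34. Cpr51A was the steadiest on its matched spots, with 1.64 ± 0.07 (SD, n = 2), whereas Cpr62Ba gave 0.92 in replicate 1 and 2.74 in replicate 2 on its valid spots. The direction of the cuticle members did not differ from that of other listed genes (Fisher's exact test, p = 0.249, adjusted 0.249).

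Junction genes were divided as well. The authors' deposited table gives the septate junction genes Cont (CG1084) at 1.26 and nrv2 (CG9261) at 0.93, and the adhesion gene ed (CG12676) at -1.61 and the polarity kinase gene aPKC (CG10261) at -1.09. Of the tracheal fate and branching list (30 genes) the authors' deposited table holds sano (CG12758) alone, at -0.94. Glutathione S-transferase genes, which serve detoxification, appear in the authors' deposited table with GstE6 (CG17530) at 1.39, GstE7 (CG17531) at 1.09, GstE1 (CG5164) at 0.71 and GstT3 (CG1702) at -0.70. GstE7 averaged 1.94 in replicate 1 and 0.23 in replicate 2 on its matched spots, and the spots of GstE6 and GstT3 lie within 2 spot pairs of each other. The authors' deposited table has the cytochrome P450 genes Cyp6a20 (CG10245) at 1.31 and Cyp312a1 (CG5137) at -1.19, and the small heat shock genes Hsp23 (CG4463) at 1.27 and Hsp26 (CG4183) at -0.91. No oxidative stress defence, endoplasmic reticulum stress, apoptosis, cell cycle, insulin and FOXO, lipid metabolism, extracellular matrix or actin gene of the fixed lists is listed. As for the pathway lists above, this does not show that these genes were unchanged.

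Each of 4 housekeeping groups held 1 to 4 listed genes. In the authors' deposited table the ribosomal protein genes RpL22 (CG7434), sta (CG14792) and RpL7A (CG3314) are lower, at -1.14, -0.95 and -0.65, and RpS15Aa (CG2033) is higher at 0.75. The authors' deposited table gives the respiratory chain genes ox (CG8764) at 0.90, ND-49L (CG11913) at 0.72 and ND-30 (CG12079) at 0.61, the proteasome genes Prosalpha1R (CG30382) at 0.63 and Rpt6 (CG1489) at -0.84, and the glycolytic gene Gapdh2 (CG8893) at 0.69. Gapdh2 is 1 of 10 matched genes that sit at the same position of different array blocks, and its log2 ratio was 0.63 after the position's median over unmatched spot pairs had been subtracted, or 0.37 with the median over all spot pairs, itself and the other 9 genes included. The spots of ND-49L lie within 2 spot pairs of those of another listed gene, alpha-Man-Ib.

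Markers of other cell types that a dissected trachea could carry were listed in small numbers. The authors' deposited table has the larval fat body storage protein gene Lsp2 (CG6806) at -0.86, and its matched spots were below 0 on each of the 4 arrays. The spot pairs beside those of Lsp2 and Tsf1, both on the fat body list, also belong to listed genes of the same direction. In the authors' deposited table the hemocyte marker genes NimB2 (CG31839) and atilla (CG6579) are given as 0.80 and 0.74, the muscle gene Mf (CG6803) as -1.09 and the gut protease gene Jon99Fi (CG18030) as -1.58. The authors' deposited table gives the neuron list members Ddc (CG10697) and fne (CG4396) as 1.92 and -0.95. Ddc encodes dopa decarboxylase, which also acts in cuticle hardening. The authors' deposited table further has CrebA (CG7450), a secretory gene regulator on the salivary gland list, at 1.05 and the nuclear receptor gene Hr39 (CG8676), on the ecdysone list, at -0.86.

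Tested gene by gene, no spot pair passed. Of 16224 spot pairs limma called 0 at an adjusted p under 0.05, and 580 had an unadjusted p under 0.05 where 811.2 are expected by chance. This comparison with chance depended on the processing. The count was 1122 with each array centred on its median, 779 with arrays also scaled, and 916 with in-block position medians subtracted. The one-class SAM-type statistic over the 4 arrays, which counts technical arrays as separate replicates, called 1 spot pair, that of CG11983. After each array had been centred on its median limma called 9, 6 higher and 3 lower. Of these CG11983 alone is matched to a listed gene (log2 ratio 2.32, adjusted p = 0.0404 in limma). Both calls of CG11983 rest on a spot at 4.20 on the technical array of replicate 1 that the authors left out. Without it CG11983 was at 0.05 on that array. The fits were repeated without all 19 located spots that the authors left out, this one among them. The adjusted p of CG11983 in limma after centring was then 0.239, and the SAM-type statistic called 0 spot pairs. The centred fit called 7, none matched to a listed gene. An unmatched spot pair whose own values were unchanged was also no longer called. Among the 131 matched genes 33 had an unadjusted p under 0.05 in limma. With p adjusted over the list alone, both matched antimicrobial peptide genes passed (the larger adjusted p in limma was 0.00755, or 0.00555 on the authors' valid spots), as did 2 of 6 matched cuticle genes, of which 0 passed on the authors' valid spots (smallest adjusted p 0.0509 in limma). These lists hold only matched members of a list the authors chose on these arrays and are not independent evidence.

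The genes with a symbol in the gene table, the smallest p in each direction and 1 sign on 4 arrays are given as values. On the higher side they were CG11983, with 2.32 ± 0.15 (SD, n = 2) and an unadjusted p of 0.00194 in limma, or 1.80 ± 0.58 and 0.00869 without the spot the authors left out, AttC, CG15096 at 1.94 ± 0.16, CG4757 at 1.87 ± 0.31, AttA, Cpr51A, the non-coding RNA gene lncRNA:CR32368 at 1.64 ± 0.24, CG15282 at 1.77 ± 0.80, CG1532 at 1.63 ± 0.52 and Cpr62Ba. CG15282 and CG1532 lie side by side on the array. On the lower side they were snoRNA:U29:54Ed at -1.65 ± 0.26, Lcp2 at -1.34 ± 0.40, CG4281 at -1.24 ± 0.07, Jon99Fi at -1.58 ± 1.35, RpL22 at -1.14 ± 0.44, gkt at -1.12 ± 0.66, brat at -1.04 ± 0.56, CG7214 at -0.88 ± 0.32, CG4502 at -0.95 ± 0.78 and Lsp2 at -0.86 ± 0.48. CR40456, with -0.97 ± 0.83 (SD, n = 2) and an unadjusted p of 0.0995 in limma, smaller than those of CG4502 and Lsp2, has no symbol there and was left out by the rule. Here gkt encodes a DNA repair phosphodiesterase and brat a translational repressor.

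**Figure D2:**
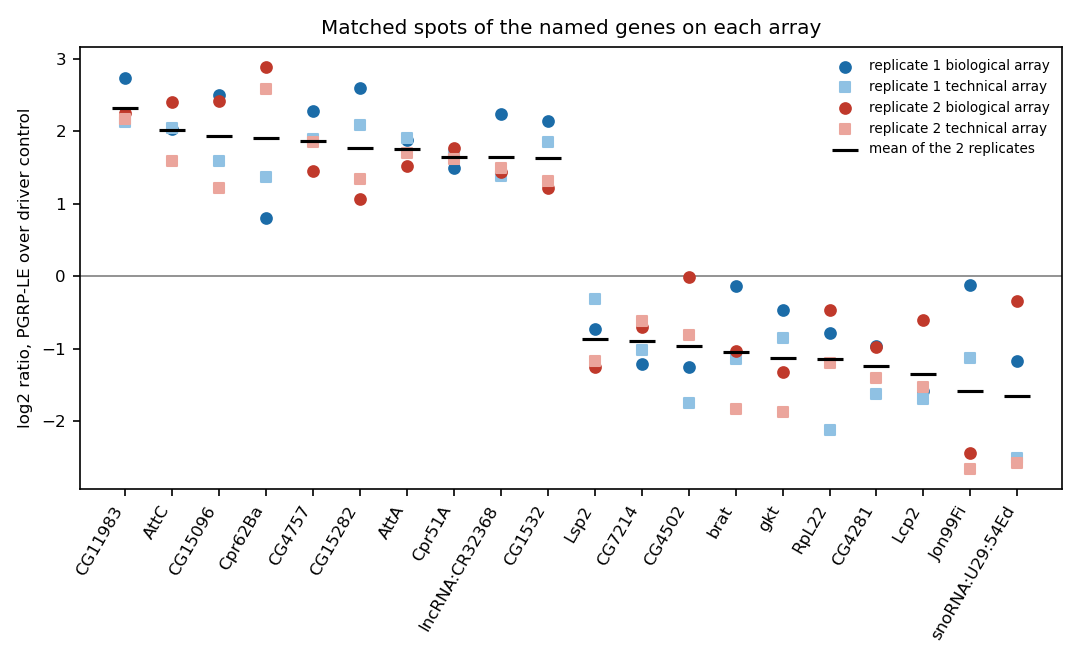
Log2 ratio (PGRP-LE over driver control, y axis) of the matched spots of the 20 genes with a symbol and the smallest p in each direction, on the biological (circles) and technical (squares) arrays of replicate 1 (blue) and replicate 2 (red), with black dashes for the mean of the 2 replicates; both duplicate spots are averaged, including the spot the authors left out for CG11983, AttA and Cpr62Ba. AttC and AttA stay above 1.5 on each array, while Jon99Fi ranges from -0.62 in replicate 1 to -2.54 in replicate 2 as replicate means.

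Agreement between the replicates was weak across the array. Of the 131 matched genes, 131 had 1 sign in both replicates and 121 on 4 arrays. The authors chose them on these same arrays by thresholds not given, and no listed gene has a quotient of standard deviation and mean above 0.97. Across all 16224 spot pairs the mean log2 ratios of the replicates were nearly unrelated (Pearson r = 0.031, Spearman rho = 0.017), and across the 2178 spot pairs with close duplicates r was 0.125. Without the matched genes, 16093 spot pairs gave r = 0.016. Single arrays correlated between -0.134 and 0.156 across spot pairs. The lowest value was that of the 2 arrays of replicate 1, and the 2 arrays of replicate 2 gave 0.009. The highest was between the technical arrays of different replicates. In spot pairs with close duplicates the arrays of replicate 1 gave 0.093 and those of replicate 2 gave 0.306. The SD over 2 replicate means does not show this disagreement within replicates. Duplicate spots on 1 array correlated between 0.307 and 0.555. Spot pairs are not independent replicates, so these values describe the arrays only. The array medians were 0.98 and -0.39 in replicate 1 and -0.07 and -0.41 in replicate 2, taken over single spots. After duplicate spots had been averaged, the array medians had a mean of 0.26 in replicate 1 and -0.27 in replicate 2. All 131 matched genes kept their direction with arrays centred and scaled. This is a weak test. Centring hardly moves a mean, since the offsets of the 4 arrays nearly cancel (AttC was at 2.015 before and 2.019 after). No listed mean is below 0.59 in size, and 121 of the genes had 1 sign on 4 arrays, so few directions could have turned.

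**Figure D3:**
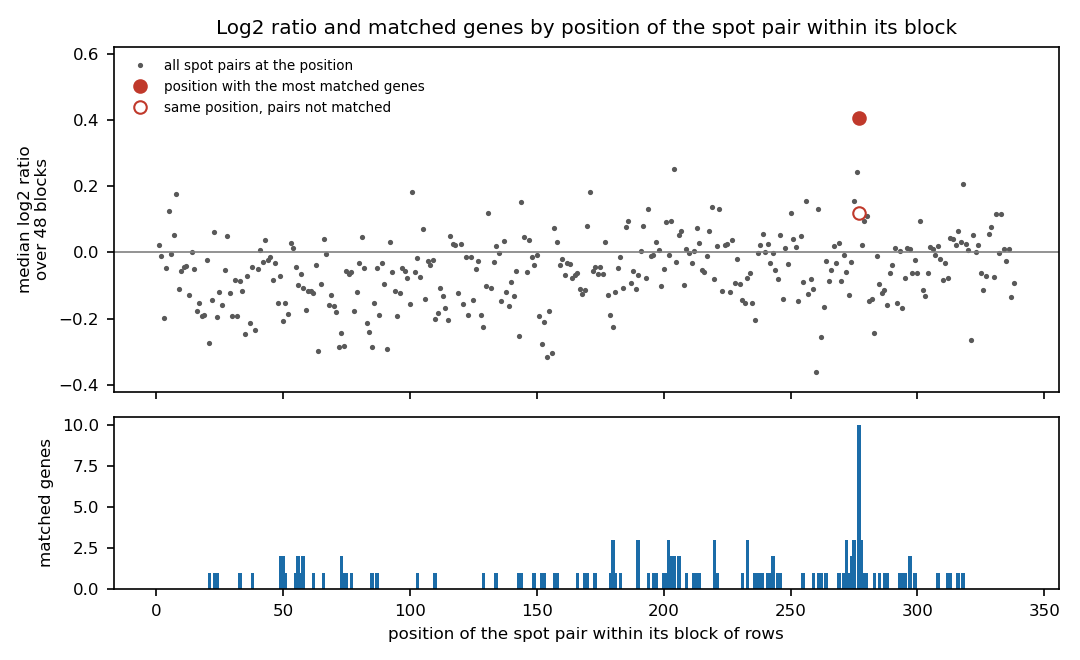
Median log2 ratio over the 48 array blocks (upper panel, y axis) and number of matched genes (lower panel, y axis) by position of the spot pair within its block (x axis). Position 277 has the highest median, 0.41, and holds 10 matched genes, while its 38 pairs not matched to a listed gene have a median of 0.12.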

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

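All tests in this part were chosen after the values had been seen, apart from the search for arrays that stand apart. Among the 36 named genes with matched spots, 3 had an outlying array by Dixon's test, where chance gives about 1 in 20. For these, the gap to the nearest other array, divided by the range of the 4 arrays, exceeded the 95% critical value for 4 values. The hemocyte marker gene atilla had a log2 ratio of -0.02 on the technical array of replicate 2, against 0.94 to 1.04 on the others. Lcp2 was at -0.60 on the biological array of replicate 2 and between -1.68 and -1.52 elsewhere. The non-coding RNA gene lncRNA:CR32368 was at 2.24 on the biological array of replicate 1 and between 1.38 and 1.5 elsewhere.

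The 9 antimicrobial peptide genes that the authors listed are all given as higher, the other 12 of the fixed list not being listed, and technical explanations were tested on AttC and AttA, the members with matched spots. An offset of their print positions shared by the blocks is too small to be the whole cause, since the highest position median is 0.41. Their median was 1.80 after each position's median over all spot pairs had been subtracted, compared with 1.88 before (SD between replicates 0.115). With the median over unmatched pairs it was 1.83. The subtraction could not have removed a ratio of this size, and it does not test a local effect within 1 block. Dye bias would turn the ratio between the dye-swapped arrays of replicate 2, but the median of the lower array was 1.55, with AttC at 2.40 and 1.60 and AttA at 1.52 and 1.70. Both genes come from a list chosen on these same arrays, where a ratio that turned with the dyes was less likely to be listed. The sign on these arrays is therefore not independent evidence. More fat body, which also makes these peptides, could not be settled: its marker Lsp2 is at -0.86, but 2 of 18 fat body markers are listed and the other one, Tsf1, is at 0.70. Induction by the receptor within the tracheal cells stays a hypothesis, since fat body and other cell types were not excluded. The 2 listed hemocyte markers, NimB2 and atilla, are given as higher, at 0.80 and 0.74. The genes were also picked by the authors on these same arrays.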

How the results depend on the processing

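The settings that kept only spot pairs with close duplicates or the authors' valid spots, subtracted position medians, used the authors' means or compared centred calls with the list were added after the data were seen. The count of spot pairs called was 0 under 16 of the 19 alternatives. It was 9 with each array centred on its median and 7 with centring on the authors' valid spots, and the cause was not tested. The SAM-type statistic called 1, CG11983, and 0 on the authors' valid spots. Without each single array the limma count stayed at 0, with 281 to 970 spot pairs at an unadjusted p under 0.05. In the simulations over all spot pairs limma called 0% of changes of 1 as deposited and 0.5% centred. The listed medians are 0.92 and -0.91, so repeated counts of 0 do not show that genes were unchanged. The median of the 2 matched antimicrobial peptide genes, 1.88, lay between 1.80 and 1.96 when an array or a replicate was left out. It kept its direction under all 15 alternatives. Over the authors' means of all 9 listed members it was 1.48, which has other members. AttC and AttA lie above 1.5 on each array, so leaving out arrays or subtracting position medians could not have turned their direction. Fits of separate arrays, with a replicate block or with a dye term, give the same mean by construction. Agreement between replicates was 0.031, which centring cannot change, and 0.125 in spot pairs with close duplicates. Overlap of called genes with the authors' deposited list was 0 at a threshold of 0.1 and 1 (CG11983) after centring, or 0 on valid spots. Values being complete, requiring a single array per replicate changes nothing. Not run, since unlisted spots have no names, were the camera and fry tests of list shifts, their estimated correlation and all settings for PGRP-LE. With 1 replicate left the count of spot pairs called has no test. Signal over background was not used here.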

Other observations

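The genes in this paragraph were chosen after their values had been seen and belong to none of the fixed lists. The authors' deposited table has Listericin (CG9080), an antibacterial protein gene that PGRP-LE is known to control, at 1.48, and its matched spots averaged 2.04 in replicate 1 and 0.93 in replicate 2. Secreted carrier protein genes appear in the authors' deposited table with Obp83b (CG11422) at 1.67, Obp56a (CG11797) at 1.30 and EbpIII (CG11390) at 0.82. Obp83b averaged 2.88 in replicate 1 and 0.46 in replicate 2, and the spot pair beside it belongs to another listed gene, CG11413. The authors' deposited table gives the neighbouring tetraspanin genes Tsp42En (CG12839) and Tsp42Ep (CG4471) at 1.60 and 1.36, the malic enzyme gene Men (CG10120) at 1.63 and the ferritin gene Fer1HCH (CG2216) at 0.82. Lower in the authors' deposited table are lncRNA:roX2 (CR32665), a dosage compensation RNA made in males, at -0.95, and the BMP ligand gene gbb (CG5562) at -0.77.

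The tests below were chosen after the patterns had been seen. At position 277 of 338 within the blocks lie 10 of the 131 matched genes, where 0.39 are expected: CG8891, CG8892, CG30183, CG30178, CG8927, CG11858, RIOK2, ArgRS, Gapdh2 and TTLL1A, all given as higher in the authors' deposited table, at 0.59 to 0.98. Chance placement is argued against (permutation p = 0.0001, the smallest that 10000 draws can give), as it is for the 35 matched genes within 2 spot pairs of another, where chance gives 4.2 (permutation p = 0.0001, again the smallest), and at most 2 of the 10 lie within 50 neighbouring genes of a chromosome. Counting these 10, 24 matched genes lie within 5 positions of 277, where 4.3 are expected, so the pattern is not confined to 1 position. An offset of the print position stays open. The median of its unmatched pairs ranked 16 among 338 positions. The neighbouring position 276, which holds no matched gene, had the highest such median, 0.244. The medians of the positions had an SD of 0.106, against 0.081 with pairs shuffled within blocks (at most 0.09 in 100 shuffles). Over all pairs at position 277 the block-centred medians were -0.17 and 0.23 on the biological arrays of replicates 1 and 2. On their technical arrays they were 0.65 and 0.60. Once each block had been centred, 9 of the 10 genes and 113 of all 131 were at 0.59 or more in size. After a further 0.07, the position's offset over its 38 unmatched pairs, had been subtracted, 9 and 114 were. With the offset over all 48 pairs, 0.33, which the 10 genes themselves raise, only 1 of the 10 was. The offset over unmatched pairs is in turn lowered by leaving out genes listed as higher, so neither value settles the question. A local effect on the array may add to an offset of the position. Neighbouring spot pairs correlated at 0.265 to 0.370 per array and pairs 50 apart at 0.082 to 0.221. Of 27 nearby couples of matched genes, 25 share their direction, against 18.3 with directions permuted (permutation p = 0.0081).

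Chance agreement of the 4 arrays was examined by turning the sign of arrays and counting spot pairs with a mean of at least 0.59 in size and a standard deviation below it. In the 2178 centred spot pairs with close duplicates the real signs gave 159 and the highest other pattern 87, so 1 of the 8 patterns, the real one, reached 159. With 8 patterns no share under 0.05 can be had. The real signs did not lead in the other counts. Over all 16224 centred spot pairs they gave 1217 against up to 1976. As deposited they gave 139 against up to 182 in the spot pairs with close duplicates, and 892 against up to 3401 over all. In both counts as deposited the leading pattern had the signs of the array medians, 0.98, -0.39, -0.07 and -0.41. Array offsets alone favour that pattern, so the counts as deposited cannot judge agreement of the arrays.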
